A study of Zea mays with 18 samples.

How the data were processed

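The labels describe 18 samples of maize B73 seedlings, from 3 organs and 2 treatments with 3 biological replicates each: primary roots, shoots and 1st leaves, grown with 1 nM epibrassinolide (EBL) for 48 h or as controls. Total RNA was extracted with TRIzol and treated with DNase, and stranded polyA libraries were made with a TruSeq kit, per the labels' protocols. The deposited table holds RPKM values (reads scaled to the length of a feature and to the size of a library) made by the authors, with 6 value columns, 1 per organ and treatment, per the file headers. How the authors combined the 3 replicates of a group, and whether libraries were scaled to each other, is not given in the sources used here. The tools named are CASAVA 1.8, Trimmomatic 0.33, TopHat2 2.0.13 and Cufflinks 2.2.1, with the genome build B73 RefGen_v4, per the submitters' processing notes, which give no roles.

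Before the data were examined, the groups, the processing alternatives, the tests and the rule for named genes were fixed. The planned tests were limma models on the log2 values of single libraries, with 26 gene lists. They could not be run, because the table holds 1 value per group; the tests that need replicates, and the analyses by list, were replaced by a rule of size. No p-value, standard deviation or interval is therefore given, the depth is unknown, and RPKM values do not show how many reads lie behind a value. Scaling by length and by a column's total makes a value depend on the other features of that column, so that a rise of a few abundant transcripts lowers all others. A value of exactly 0 can be a failed estimate, so such features are described as listed at 0 and get no fold.

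Features were compared within an organ when at least 1 of the 6 columns reached 1 RPKM and both columns of the organ were above 0. The effect of EBL is the log2 ratio of EBL to control after adding a pseudocount of 1 to each value, so that a fold is on the log2(value + 1) scale and understates changes at low values. A gene model was counted as higher or lower when the effect was at least 1 in size, a 2-fold change. Counts of gene models cover the Zm00001d identifiers, and miRNA genes were treated apart.

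The planned rule for named genes took, per organ, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with a mean of at least 5 and a symbol, and, for identifiers without a name, at most 2 that rose and 2 that fell. It was applied with the size rule in place of the adjusted p-value and of the agreement of replicates. Names came from a RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, a different build from that of the authors, so no coordinates are given. It matched 153 of 45260 features, all miRNA genes, and 0 gene models. For the same reason the 26 gene lists, which covered hormone pathways, cell walls, photosynthesis, the cell cycle, stress and organ markers, had 0 matched members and gave no result.

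Organ-enriched groups were defined after the data were seen. A gene model was enriched in an organ when the mean of its control and EBL log2 values there was at least that of 10 RPKM and at least 8-fold above each other organ. The median effect of a group in an organ is given with its percentile among 10000 random lists of the same size, drawn within 10 bins of mean expression. The number expected for independent lists is the product of the sizes of both sets over the number of gene models compared.

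Each result was recomputed with pseudocounts of 0.1 and 2, without the minimum of 1 RPKM, with a mean of at least 5 RPKM, after median-ratio scaling and after quantile normalization. Added after the data were seen were a scaling to the sum of the gene models, the inclusion of features listed at 0 in 1 column, the removal of organ-enriched gene models, and organ groups defined without the organ measured. The size rule was tested on simulated data, with 200 gene models per organ changed by a known fold and noise of 0.15 (log2 SD). The changed ones were drawn only from gene models with at least 5 RPKM in the control column, so recovery at lower levels was not tested. For a 2.5-fold change it recovered 90.5% of the 200 in roots, 91.0% in shoots and 91.5% in leaves, with 25710, 25848 and 25534 gene models compared. For a 4-fold change it recovered 100% in each organ. For a 1.5-fold change it recovered 0.5% in shoots and 0% in roots and leaves. The noise was assumed, was the same in each organ and was narrower than the spread of the observed effects. The simulation therefore gives neither a rate of false calls nor the recovery at the observed spread, and it does not compare the organs. The interquartile range of those effects was 0.29 in roots, 0.27 in shoots and 0.56 in leaves. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.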

Results

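Transcript levels were measured by polyA RNA sequencing in seedlings of the maize inbred line B73 treated with a brassinosteroid. Brassinosteroids are plant steroid hormones that promote cell elongation, and the one applied was epibrassinolide (EBL), at 1 nM for 48 h, after 3 days of germination in the dark. Primary roots, shoots (stem, apex and coleoptile) and the 1st leaf were collected from EBL-treated and control seedlings, with 3 biological replicates in each of the 6 groups, 18 samples in all. The study asked how brassinosteroid affects growth, the response to gravity and gene expression in these organs. The values analysed are RPKM, 1 value per group and feature as the authors gave it. No replicate error can therefore be attached to any value, and no test within an organ or of a difference between organs could be run. A test of an EBL effect common to the 3 organs, paired by organ, was not run. The depth of the libraries is unknown from these values. The columns summed to 952314 RPKM in control roots and 962061 in EBL roots, to 934116 and 1026860 in shoots, and to 1284512 and 1599725 in leaves.

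The table listed 45260 features, of which 43484 were gene models, 1448 were non-coding RNA features with ENSRNA identifiers, 174 were features with GRMZM5G identifiers and 154 were microRNA (miRNA) genes. A gene model reached 1 RPKM in 23292 cases in control roots, 22741 in control shoots and 21567 in control leaves, and in 23457, 22568 and 21846 cases in the EBL columns. The ENSRNA features took 5.55% of the summed RPKM in control roots and 7.93% in EBL roots, 8.24% and 9.72% in shoots, and 21.5% and 21.3% in leaves. The 10 most abundant features took 21.95% of the sum in control leaves, against 5.43% in control roots. A symbol could be attached to 153 features, all of them miRNA genes, so the gene models are given by identifier and are described below mainly by the organ in which they were enriched.

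The organs differed far more from each other than EBL columns did from control columns. Spearman's rank correlation across 26152 gene models, which are not independent replicates, was 0.781 between control roots and control shoots, 0.742 between control shoots and control leaves and 0.607 between control roots and control leaves. Between the control and EBL columns of one organ it was 0.976 in roots, 0.987 in shoots and 0.959 in leaves. In the control columns 393 gene models had at least 10 RPKM in roots and were at least 8-fold higher there than in both other organs. By the same rule 100 were enriched in shoots and 332 in leaves, with the fold on the log2(RPKM + 1) scale. Of these, 318 were also root-enriched by that rule in the EBL columns (80.9%), 63 were also shoot-enriched (63.0%) and 278 were also leaf-enriched (83.7%). Among the miRNA genes, MIR164b, whose family targets NAC transcription factors of organ boundaries, stood at 335 RPKM in control roots, 292 in control shoots and 53.6 in control leaves. MIR171f stood at 156, 20.9 and 7.84 RPKM in the same columns, and MIR169i at 2.89, 3.89 and 116 RPKM. These organ values for named miRNA genes were chosen after the values were seen.

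The first comparison asked what EBL did to transcript levels in primary roots. More gene models were lower than higher: of 25741 compared, 415 were at least 2-fold lower in EBL roots and 155 at least 2-fold higher, together 2.21%. Gene models enriched in leaves made up 130 of the 415 lower ones (31.3%), against 5.71 for independent lists. Of the 354 leaf-enriched gene models compared in roots, 292 were lower in EBL and 62 higher, and their median RPKM was 3.52 in control roots and 1.48 in EBL roots. Gene models enriched in shoots went the other way: 62 of 69 were higher in EBL roots, and 8 of them passed 2-fold upward against 2 downward.

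The median effect of the leaf-enriched gene models in roots was -0.52 (log2), below that of every one of 10000 random lists matched on mean expression, whose median was 0.05. That of the shoot-enriched gene models was 0.31, above all 10000 random lists, and that of the root-enriched gene models was 0.07, at percentile 99.9. The shoot-enriched ones stood low in roots, at a median of 0.291 RPKM in control and 0.840 in EBL. In shoots their median was 46.1 RPKM in control and 48.7 in EBL. Whether shoot RNA in the EBL root material could account for their rise in roots was not tested. For the root-enriched ones the median RPKM was 39.2 in control and 36.7 in EBL, with 19 past 2-fold downward and 7 upward. Their median effect was 0.002 under median-ratio scaling. These percentiles are a description of these libraries. When the groups were defined from the other 2 organs alone, an alternative added after the data were seen, the medians in roots were -0.33 for leaf-enriched and 0.16 for shoot-enriched gene models; with a pseudocount of 0.1 they were -1.09 and 0.90, and with 2 the latter was 0.20. The gene models with the largest falls in roots were Zm00001d046170, at 58.2 RPKM in control and 2.81 in EBL, and Zm00001d044099, at 66.7 and 4.17. Zm00001d046170 was listed at 0 in control leaves and stood at 3954 RPKM in EBL leaves. Zm00001d044099 stood at 5628 RPKM in control leaves and 5270 in EBL leaves. The largest rises were those of Zm00001d027192, from 0.296 to 12.8 RPKM, and Zm00001d043049, from 1.01 to 13.8. Zm00001d043049 stood at 733 RPKM in control shoots. Without the gene models enriched in any organ, an alternative added after the data were seen, 264 gene models were lower and 139 higher. The counts depended on the pseudocount, with 767 lower and 476 higher when 0.1 was added in place of 1.

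In EBL roots 5 miRNA genes were at least 2-fold higher and 4 at least 2-fold lower. MIR396e, of the family that targets growth-regulating factors, rose from 8.10 to 28.1 RPKM (log2 change 1.68). MIR166d, whose family targets class III homeodomain-leucine zipper genes, rose from 25.8 to 56.7 RPKM (1.10), and MIR397a, of a family that targets laccases, from 6.39 to 14.8 (1.10). MIR160b, of a family that targets auxin response factors, rose from 22.02 to 46.4 RPKM (1.04), and MIR156d, of a family that targets SPL transcription factors, from 3.42 to 7.90 (1.01). MIR167b, of another family that targets auxin response factors, fell from 24.9 to 0.0125 RPKM (-4.67, or -7.79 with a pseudocount of 0.1 and -3.74 with 2). The EBL value of MIR167b is as doubtful as a listing at 0. MIR393b, whose family targets the auxin receptors, fell from 16.1 to 5.14 RPKM (-1.48), MIR169c, whose family targets NF-YA transcription factors, from 16.7 to 6.06 (-1.33) and MIR169e from 7.91 to 2.80 (-1.23). MIR399g, of the phosphate starvation family, was listed at 0 in control roots and at 36.6 RPKM in EBL roots, and MIR408b at 0 and 12.2. In all, 9 of the 22 miRNA genes compared in roots passed 2-fold. MIR160b was at 0.97 (log2) under median-ratio scaling, and MIR156d fell short of 2-fold under median-ratio scaling (0.91) and a pseudocount of 2 (0.87) and, by a small margin, after quantile normalization.

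In shoots the response to EBL was the smallest in number, with 111 gene models lower and 33 higher of 25599 compared (0.563%). Gene models enriched in roots made up 45 of the 111 lower ones (40.5%), against 1.5 for independent lists, and none of the 33 higher ones. Of 347 root-enriched gene models compared in shoots, 320 were lower in EBL and 27 higher, and their median RPKM was 1.34 in control shoots and 0.632 in EBL shoots. The shoot-enriched gene models themselves were little different, with 54 of 80 higher.

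The root-enriched gene models had a median effect of -0.38 (log2) in shoots, below all 10000 random lists, and the shoot-enriched ones 0.10, at percentile 85.2, which became -0.01 when columns were scaled to the sum of the gene models. The leaf-enriched gene models had a median of -0.002 in shoots, at percentile 0.95, and 15 of them were at least 2-fold lower; defined from leaves and roots alone, their median was 0.16. The largest falls in shoots were those of Zm00001d017485, from 20.3 to 1.74 RPKM, and Zm00001d023280, from 17.2 to 1.42. In control roots these gene models stood at 1266 and 835 RPKM. Zm00001d001075 rose from 0.151 to 64.1 RPKM in shoots and Zm00001d017104 from 1.68 to 21.9. Without organ-enriched gene models the shoot counts were 50 lower and 32 higher, and with a pseudocount of 0.1 they were 534 and 178. When the group was defined from roots and leaves alone, the root-enriched median in shoots was -0.05, and it was -0.78 with a pseudocount of 0.1 and -0.25 with 2.

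**Figure D1:**
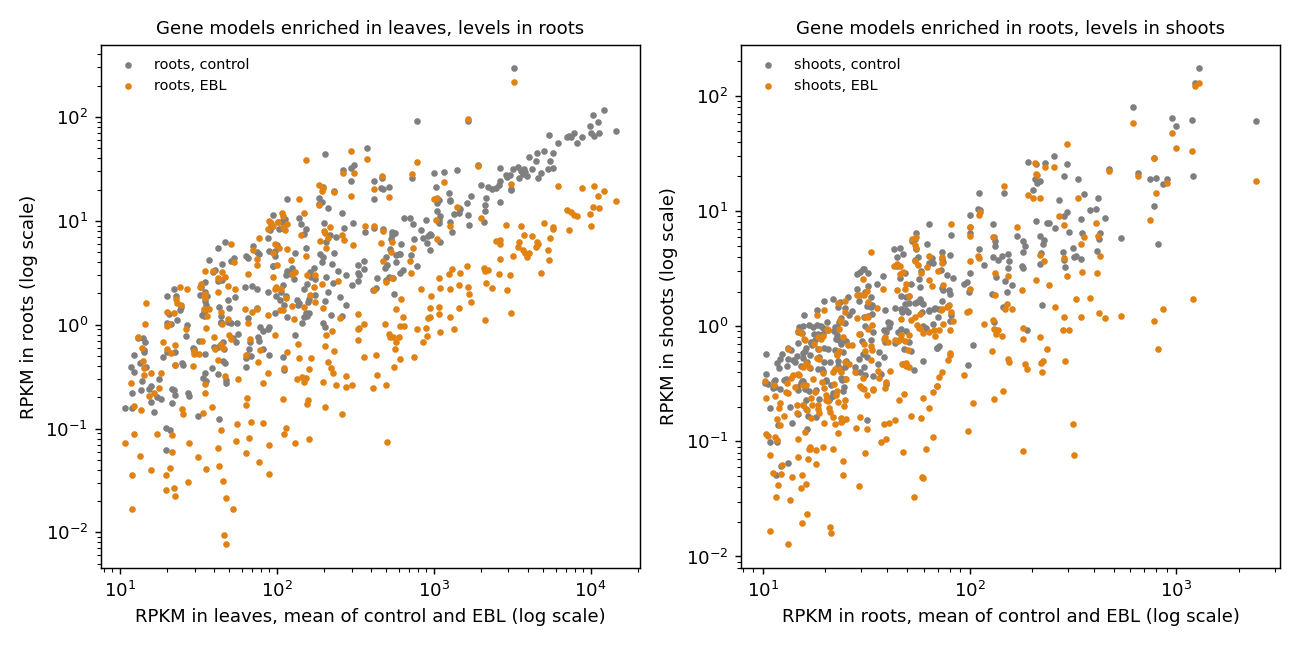
Left, RPKM in control roots (grey) and EBL roots (orange) of the 354 gene models enriched in leaves, against their mean RPKM in leaves; right, RPKM in control and EBL shoots of the 347 gene models enriched in roots, against their mean RPKM in roots. Each point is 1 gene model in 1 column and all axes are logarithmic; 292 of the gene models on the left and 320 on the right were lower in the EBL column.

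Among miRNA genes in shoots, 6 were at least 2-fold higher in EBL and 3 at least 2-fold lower of 26 compared. MIR171d, whose family targets GRAS transcription factors that maintain meristems, rose from 5.64 to 32.4 RPKM (log2 change 2.33) and MIR171e from 4.14 to 11.1 (1.23). MIR396d rose from 4.44 to 23.5 RPKM (2.17) and MIR396e from 3.40 to 11.8 (1.54), while MIR396c of the same family fell from 69.8 to 13.9 (-2.25). MIR166d rose from 6.31 to 18.5 RPKM (1.42) and MIR394b, of a family that acts in the shoot meristem, from 7.71 to 21.9 (1.40). MIR160c fell from 18.1 to 4.88 RPKM (-1.70) and MIR160b from 12.1 to 0.000517 (-3.71, or -6.92 with a pseudocount of 0.1 and -2.81 with 2). The EBL value of MIR160b is as doubtful as a listing at 0. MIR156e was listed at 11.8 RPKM in control and at 0 in EBL shoots, MIR171m at 15.4 and 0, and MIR399g at 0 and 25.1.

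In leaves the number of gene models that differed was the highest of the 3 organs, and most were higher in EBL as the authors scaled the values: of 25458 compared, 1229 were higher and 241 lower (5.77%). When the columns were scaled so that the gene models summed to the same total, which lowered the median effect of all gene models in leaves to -0.23 (log2), 561 were higher and 762 lower. The leaf-enriched gene models included 48 of the 1229 higher ones, against 17.6 for independent lists, and 5 of the lower ones. Of 364, 264 were higher in EBL leaves, and their median RPKM was 127 in control and 163 in EBL. Shoot-enriched gene models were also higher in EBL leaves, 53 of 69. Their median RPKM there was 1.22 in control and 1.72 in EBL, and shoot RNA in the EBL leaf material was not tested as a source.

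The leaf-enriched gene models had a median effect of 0.35 (log2) in leaves and the shoot-enriched ones 0.33, both above all 10000 random lists, whose medians were 0.21 and -0.01. The former was 0.04 and the latter 0.14 when columns were scaled to the sum of the gene models, and the former was 0.06 after quantile normalization. With a pseudocount of 0.1 the latter was 0.54. The root-enriched gene models had a median of 0.01 in leaves, at percentile 88.4, and -0.04 under the scaling to the sum. The effect rose with level: the median was -0.03 for gene models under 15 RPKM and 0.38 for the 540 at 255 RPKM or more. A rise with level was also seen in shoots, where these medians were -0.01 and 0.23. In roots they were 0.06 and 0.03. The interquartile range of the effects was 0.56 in leaves, 0.29 in roots and 0.27 in shoots. Zm00001d001075, also the gene model with the largest rise in shoots, rose in leaves from 1.89 to 113 RPKM, and Zm00001d002093 rose from 11.3 to 116. Zm00001d023516 fell from 141 to 25.6 RPKM and Zm00001d043413 from 10.7 to 1.34. With a pseudocount of 0.1, 2042 gene models were higher and 623 lower.

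**Figure D2:**
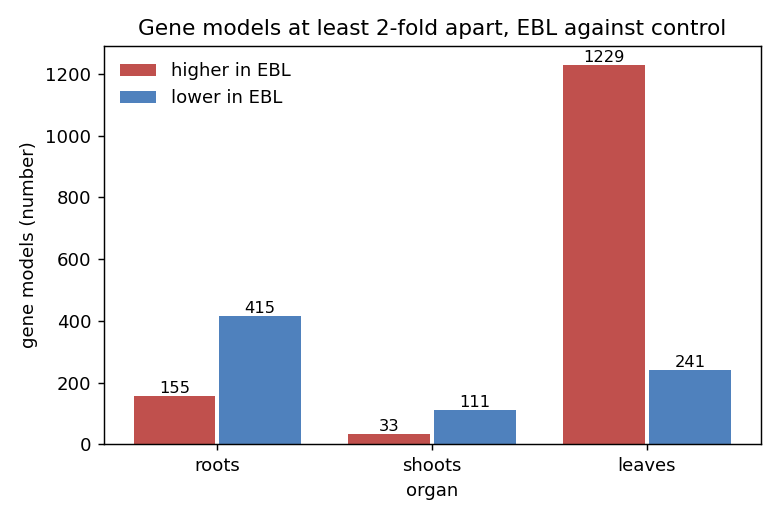
Number of gene models at least 2-fold higher (red) or lower (blue) in the EBL column than in the control column of each organ, on the log2(RPKM + 1) scale. Lower gene models outnumbered higher ones in roots (415 and 155) and shoots (111 and 33), and the reverse held in leaves (241 and 1229), where scaling to the sum of the gene models gave 762 lower and 561 higher.

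In leaves 6 of 25 miRNA genes were at least 2-fold higher in EBL and 1 was lower. MIR408b, of a copper-responsive family, rose from 29.4 to 62.3 RPKM (log2 change 1.06), MIR168a, whose family targets ARGONAUTE genes, from 3.83 to 11.2 (1.34) and MIR160b from 3.76 to 13.8 (1.64). MIR156a rose from 4.80 to 11.5 RPKM (1.11). MIR393c was at 0.0278 RPKM in control and 12.3 in EBL leaves (3.70), and MIR396e at 0.000181 and 10.1 (3.47). With a pseudocount of 0.1 these log2 changes were 6.60 and 6.66, and with 2 they were 2.82 and 2.59. Both control values are as doubtful as a listing at 0. MIR171d fell from 38.4 to 13.9 RPKM (-1.40), opposite to its rise in shoots, a difference that was not tested. MIR168b was listed at 0 in control and at 74.95 RPKM in EBL leaves, MIR171m at 0 and 38.6, and MIR396d at 0 and 15.7. When scaled to the sum of the gene models, MIR408b (0.75) and MIR156a (0.81) fell short of 2-fold; MIR408b also did after quantile normalization (0.84), and MIR156a with a pseudocount of 2 (0.99).

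At a mean of at least 5 RPKM, 9 of 22 miRNA genes in roots (40.9%), 9 of 26 in shoots (34.6%) and 7 of 25 in leaves (28.0%) passed 2-fold. The shares were 2.12%, 0.407% and 7.19% of gene models and 21.9%, 16.2% and 27.6% of ENSRNA features; differences between these classes were not tested, and an RPKM value need not rest on equal numbers of reads in each. None of the GRMZM5G features, of which 2, 10 and 32 reached that mean, passed 2-fold. The values come from polyA libraries and so describe longer transcripts over these loci, not the mature miRNAs.

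**Figure D3:**
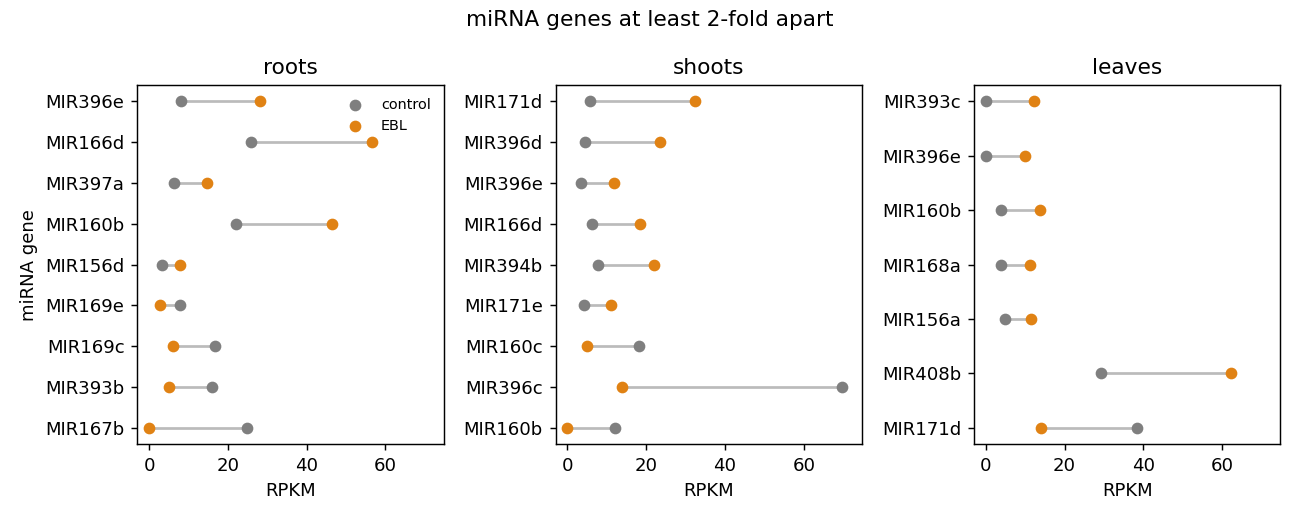
RPKM in the control (grey) and EBL (orange) columns of each miRNA gene that was at least 2-fold apart on the log2(RPKM + 1) scale, with a mean of at least 5 RPKM, in roots, shoots and leaves. MIR396e was higher in EBL in each organ, MIR171d was higher in shoots and lower in leaves, and MIR160b was lower in shoots and higher in roots and leaves. The values of MIR396e in control leaves (0.000181 RPKM) and of MIR160b in EBL shoots (0.000517 RPKM) are as doubtful as a listing at 0.

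The last comparison asked whether EBL acted alike in the 3 organs. MIR396e was at least 2-fold higher in all 3 organs, in leaves from a control value of 0.000181 RPKM that is as doubtful as a listing at 0, and MIR166d in roots and shoots, while in leaves MIR166d was listed at 0 in both columns. One gene model, Zm00001d040715, was at least 2-fold higher in all 3 organs and 2, Zm00001d020395 and Zm00001d041614, were at least 2-fold lower in all 3, of 25003 compared. These identifiers were taken because they were the whole of each count, after their values were seen. Gene models that passed 2-fold in the same direction numbered 16 in roots and shoots, 34 in roots and leaves and 22 in shoots and leaves, against 1.77, 9.50 and 2.13 for independent lists. With a pseudocount of 0.1 these were 76, 160 and 142, against 17.1, 49.0 and 23.3, and with 2 they were 8, 19 and 9, against 0.718, 4.09 and 0.708. Without organ-enriched gene models, 8 were shared by roots and shoots, against 0.570; scaled to the sum of the gene models, 52 were shared by roots and leaves, against 14.4. With features listed at 0 kept, the numbers were 34, 52 and 36, against 2.65, 12.2 and 3.73. Opposite directions were found for 2, 27 and 7 gene models, against 0.873, 19.3 and 5.17 for independent lists.

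The effect differed by at least 1 (log2) for 781 of 25354 gene models between roots and shoots, for 1967 of 25213 between roots and leaves and for 1328 of 25188 between shoots and leaves. These counts were 1926, 3341 and 2574 with a pseudocount of 0.1, and the first was 498 with 2. In the comparison of roots with leaves, the effect in leaves was the higher one for 1566 gene models and that in roots for 401, but for 862 and 930 when columns were scaled to the sum of the gene models. Spearman's correlation of the effects across gene models, which are not independent, was 0.09 between roots and shoots, 0.18 between roots and leaves and 0.34 between shoots and leaves. These are differences between single values per group, and none of them was tested.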

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

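The tests in this part were chosen after the results were seen, except that of the spread of effects in leaves after quantile normalization, which was set before its value was computed. The tests for RNA of another organ covered leaf-enriched gene models in roots and root-enriched ones in shoots. The rises of shoot-enriched gene models in EBL roots and leaves were not tested for it. The tests were first run on the 50 most abundant members of each group and then set anew, with the 60% bound, for all members. In the first form 47 of the 50 leaf-enriched members in roots lay within 2-fold of their own median, past the 40 then set, and 34 of the 50 root-enriched members in shoots did, between the bounds of 25 and 40. The groups hold 1 value each, so no sample was set against its replicates, and differences between organs were not tested.

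Some results went in opposite directions in different organs. MIR160b had an effect of 1.04 (log2) in roots, -3.71 in shoots and 1.64 in leaves, and MIR171d 2.33 in shoots and -1.40 in leaves. The shoot effect of MIR160b rests on 0.000517 RPKM in EBL, a value as doubtful as a listing at 0. Its root effect was 0.97 under median-ratio scaling. Gene models past 2-fold in opposite directions numbered 2 in roots and shoots, 27 in roots and leaves and 7 in shoots and leaves, against 0.873, 19.3 and 5.17 for independent lists. Outside the gene models and miRNA genes, the 6 ENSRNA features with at least 1000 RPKM in all 6 columns were higher in EBL in every organ as the authors scaled the values. Their median effects were 0.72 in roots, 0.50 in shoots and 0.56 in leaves. The lowest effect in leaves was 0.16. These features were not recomputed under the scaling to the sum of the gene models. That scaling moved the median effect of all gene models in leaves from -0.01 to -0.23, so their direction in leaves may depend on it.

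Leaf-enriched gene models had a median effect of -0.52 in roots, or -0.33 when defined without the root values, and 0.35 in leaves. The scaling of the root columns is argued against, because the median stayed at -0.51 or lower under every scaling tried. A candidate explanation is leaf RNA mixed into the control root material: the control level exceeded the EBL level by a median of 0.631% of the leaf level, and 58.5% of the 354 members lay within 2-fold of that share, just short of the 60% set for the test. An effect of EBL on leaf-type transcripts within root cells stays open too. The prediction written for it was a fold unrelated to the leaf level, read as a correlation of the excess with the leaf level under 0.2. That bound was not met (Spearman 0.78, and 0.73 with the shoot level). The correlation cannot decide, because the excess is a difference in RPKM, which grows with the level under a constant fold too. Such an effect might also itself follow the leaf profile. The 10 ENSRNA features called typical of leaves had at least 1000 RPKM there and were at least 16-fold above roots, a choice that used the root values and not the shoot values. They had an excess of only 0.0383% of their leaf level, although their level in control roots, 0.744% of the leaf level, would leave room for such a share.

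Root-enriched gene models were lower in EBL shoots, and scaling is again argued against, since the median closest to 0 over the scalings was -0.33. The excess in control shoots had a median of 1.22% of the root level, and 59.4% of the 347 members lay within 2-fold of it, again just short of the 60% set for the test. Root RNA in the control shoot material may account for it, which the test did not settle, and an effect of EBL on root-type transcripts in shoots was not tested and stays open. The excess followed the root level (Spearman 0.69) more closely than the leaf level (0.44). As a difference in RPKM, it cannot decide between these explanations. When the group was defined without the shoot values, the median effect was -0.05. In the same comparison the 10 ENSRNA features typical of leaves were all higher in EBL shoots, with a median effect of 0.88.

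More gene models passed 2-fold in leaves than in the other organs, and most were higher. For the direction, the scaling could not be set aside: the share of higher ones was 83.6% as the authors scaled the values, 85.6% after median-ratio scaling, 77.2% after quantile normalization and 42.4% when scaled to the sum of the gene models. For the spread, the interquartile range in leaves after quantile normalization was 1.88 times that of the wider of the other organs. It was 0.55 in leaves, against 0.56 as the authors scaled the values. This test could hardly come out otherwise, because rescaling a column shifts its effects nearly alike. Quantile normalization also keeps the order of the values within a column. No conclusion about scaling is therefore drawn from it. A stronger response of leaves to EBL and a larger difference between the leaf samples for another reason, such as stage, are both open, since no replicate values were used here.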

How the results depend on the processing

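The pseudocounts, the filters, median-ratio scaling and quantile normalization were chosen beforehand; the scaling to the sum of the gene models, the inclusion of features listed at 0, the removal of organ-enriched gene models and the other group definition were added after the results were seen. The control and EBL columns do pair by organ, but a test of EBL paired by organ was not run. No paired analysis was possible by replicate, because the columns hold 1 value per group and carry no replicate numbers. For the same reason leaving out replicates, the other variance models, the choice of libraries in the fit, the gene set tests and the overlap at an unadjusted p were not run. Each miRNA gene past 2-fold kept its direction under every scaling. This is weak evidence, because each was chosen for an effect of at least 1 (log2) and the scalings moved the values by less than that. The other alternatives could not turn the direction. In leaves the majority of gene models past 2-fold turned from higher to lower under the scaling to the sum of the gene models. Of the values of counts under an alternative, 97 were within 1.5 times the main count and 38 were not. Of those of miRNA genes, 192 were close to the main value and 8, all under another pseudocount, were not. Many of the 192 were fixed in advance, because the filters and the inclusion of features listed at 0 cannot change the value of a single gene. Of the medians of organ-enriched groups, 64 were within 1.5 times or 0.1 (log2) of the main value and 14 were not. Some of the 97 and of the 64 were fixed in advance too. With a pseudocount of 1, a gene model under 1 RPKM in every column cannot pass 2-fold. Dropping that minimum therefore cannot change the counts past 2-fold within an organ or the overlaps. It cannot change the group medians either, because members needed a level of at least 10 RPKM in their organ. The unknown depth limits low values most, and these are what the pseudocount weighs.

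With a pseudocount of 0.1, 1243 gene models passed 2-fold in roots (476 higher, 767 lower), 712 in shoots (178 and 534) and 2665 in leaves (2042 and 623). The differences between organs then numbered 1926 for roots and shoots, 3341 for roots and leaves and 2574 for shoots and leaves, the overlaps 76, 160 and 142, and the group medians were 0.90 (shoot-enriched in roots), 0.54 (shoot-enriched in leaves), -1.09 (leaf-enriched in roots) and -0.78 (root-enriched in shoots). With a pseudocount of 2, 89 were higher in roots, 79 passed in shoots (16 higher, 63 lower) and 141 were lower in leaves; the difference of roots and shoots was 498, the overlaps 8, 19 and 9, and the medians 0.20 (shoot-enriched in roots) and -0.25 (root-enriched in shoots). Both follow from the weight given to low values. With a mean of at least 5 RPKM, which tests fewer gene models, 79 were higher in roots, 21 higher in shoots and 145 lower in leaves. Scaling to the sum of the gene models gave 561 higher and 762 lower in leaves and an overlap of 52 for roots and leaves. The medians became 0.045 (leaf-enriched in leaves), 0.14 (shoot-enriched in leaves) and -0.011 (shoot-enriched in shoots). In leaves this scaling lowers the EBL column against control by construction. The columns summed to 1284512 RPKM in control and 1599725 in EBL leaves, with 78.4% and 78.6% in gene models. Quantile normalization gave a median of 0.057 (leaf-enriched in leaves). The causes of that median and of the overlap were not tested. Keeping features listed at 0 gave 64 higher in shoots and overlaps of 34, 52 and 36, because more features entered. Without organ-enriched gene models, 264 were lower in roots, 82 passed in shoots (50 lower) and the overlap of roots and shoots was 8, because these gene models were among those counted. Groups defined without the organ measured had medians of -0.33 (leaf-enriched in roots), 0.16 (leaf-enriched in shoots), -0.052 (root-enriched in shoots) and 0.16 (shoot-enriched in roots); the cause was not tested.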

Other observations

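The tests in this part were chosen after the results were seen. Several features were abundant in one column of an organ and listed at 0 in the other; they were singled out after their values were seen. Zm00001d046170 was listed at 0 in control leaves and at 3954 RPKM in EBL leaves, while it stood at 158 and 92.7 RPKM in control and EBL shoots. Zm00001d038163 was listed at 0 in control leaves and at 3265 RPKM in EBL leaves, and at 264 and 182 RPKM in shoots. ENSRNA049478180 stood at 2529 RPKM in control roots and 2349 in control shoots and was listed at 0 in the other 4 columns. Among gene models, 270 in roots, 389 in shoots and 406 in leaves were listed at 0 in 1 column of the organ, and 38, 36 and 46 of these had at least 10 RPKM in the other.

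At a mean of at least 5 RPKM, 26 of 32 GRMZM5G features had an effect below 0 in leaves, with a median of -0.46 (log2), and 9 of 10 had one above 0 in shoots, with a median of 0.15; none passed 2-fold in either organ. The 10 ENSRNA features typical of leaves, with at least 1000 RPKM there and at least 16-fold above roots, were higher in EBL leaves in 5 of 10 cases and in EBL roots in 4 of 10.

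Gene models with consecutive identifier numbers passed 2-fold together more often than shuffled calls did in some comparisons. In roots 19 of 14400 consecutive pairs were both lower, against a mean of 3.79 and a highest value of 12 in 1000 shuffles, and in shoots 7 of 14250, against 0.268 and 3. Those in shoots included runs of root-enriched gene models, such as Zm00001d047113 to Zm00001d047117. Those in roots included the leaf-enriched Zm00001d035001 to Zm00001d035003. The shuffles ignored these groups, so the pairs are not separate from the falls of organ-enriched gene models. In leaves 51 of 14098 pairs were both higher, against a mean of 32.7 and a highest value of 55.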
